A study of Homo sapiens with 4 samples.

How the data were processed

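SMARCB1 and H3K27ac were measured by ChIP-seq in SK-Hep1 cells. Libraries were grouped from the titles given by the submitters into SMARCB1 ChIP, H3K27ac with a control shRNA and H3K27ac with an shRNA against SMARCB1, with 1 library per group. An input library is also labelled in the series and was not analysed here. Per the labels, chromatin was sheared by sonication, cells expressing an shRNA were selected with puromycin, and libraries were sequenced as read pairs.

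The deposited values are peak positions. Per the submitters' processing notes, Bowtie2, HOMER and the hg38 build were used, without stated versions. Per the file headers, both H3K27ac lists were called with HOMER in its histone style, 1 library at a time, and both against the same control input. The headers give a peak size of 500 bp, a minimum distance of 1000 bp, a required 4-fold signal over input and over the local region, and stitching of peaks into regions of variable length. They also give 13235203 tags and a fragment length of 190 bp for the control library, and 10203310 tags and 158 bp for the knockdown library, a ratio of 1.30 in tags. Because the knockdown library was called against the control input, DNA copy number or open chromatin that differed between the cell populations was not subtracted. The deposited H3K27ac lists carry the same placeholder score for every peak, so width was the only size available for ranking. Each peak in the deposited SMARCB1 list has a number from 7.39 to 1217.4, whose unit is not given in the sources used here, and a position class, both the authors' own. That number was used only to rank peaks within its list, and the caller settings and depth behind it are not given in the sources used here.

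Peaks on the autosomes and X were kept, which left out 3 peaks from each H3K27ac list. Positions are printed 1-based in hg38. Peaks were compared by an overlap of at least 1 base, and these overlaps were checked with bedtools 2.31.1. Shares have 95% Wilson intervals, which cover counting error only. SMARCB1 peaks were moved 1000 times to random positions on their chromosomes to give the overlap of random positions. Genes came from the RefSeq table of GRCh38.p14, whose main chromosomes are those of hg38, with 19821 protein-coding genes after 153 records on alternate or unplaced sequences were left out. All 550 listed symbols were found. That table has no strand, transcript starts or exons, so a gene end, defined as within 1 kb of either end of the gene record, replaced the promoter set out in the plan. It therefore includes 3' ends. Exon, intron and UTR classes were taken only from the authors' SMARCB1 list.

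For peaks with and without SMARCB1, 10000 draws of peaks without it were matched on 10 width classes and on position at a gene end. Width replaced the per-peak value set out in the plan, since no H3K27ac value varied. Gene lists were set beside 10000 random lists of the same size, drawn from genes with H3K27ac at an end and matched on 5 classes of H3K27ac width there. Each random list tied with the observed one was counted as 0.5 in these percentiles, which describe the present libraries and are not tests between conditions. The overlap and matching code was tested on simulated data, and all 5000 simulated peaks were placed as shared or not shared as simulated. The matched difference had a mean of 0.0316 percentage points where 0 was simulated and 9.88 where 10 was simulated. Simulated loss and binding depended on the same width classes used for matching. The simulation therefore checks the code only, not whether matching removes differences in peak strength. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used with random seed 11.

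The 21 gene lists, the alternatives called planned and the rule for named genes were set before the data were examined. The rule took the 10 SMARCB1 peaks of highest value, 1 per nearest protein-coding gene, of which 1 is not reported here. It took the 12 genes per direction with H3K27ac at an end in 1 library only and the largest difference in covered length within 10 kb of their ends, and the 10 such control-only genes with a SMARCB1 peak at an end. From each list it took up to 4 single-library members per direction and up to 2 members marked in both. SMARCB1, NUP210 and the SWI/SNF subunit genes were taken whatever their values. UGT2B7 and the other list members marked in both were ranked by covered length. Searches for 17 motif sequences needed the genome and were not run. The alternatives covered the overlap that counts as shared, wider peaks only, merging of neighbouring peaks, the sequences kept, the gene end window and the matching.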

Results

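H3K27ac, a histone mark of active promoters and enhancers, was profiled by ChIP-seq in SK-Hep1 cells, a human hepatic adenocarcinoma line, with a control shRNA and with an shRNA against SMARCB1, a core subunit of the SWI/SNF chromatin remodelling complexes. Another ChIP-seq library profiled SMARCB1 itself, and its labels do not say which shRNA those cells carried. Each group had 1 library, so none of the values below has a replicate check and no test between conditions was made. The intervals given are 95% Wilson intervals and cover the counting of peaks only. The control H3K27ac library held 13235203 tags, with 53.8% of them in peaks, and the knockdown library held 10203310, with 55.1% in peaks. The depth of the SMARCB1 library was not given in the sources used here. The lists held 35307 control H3K27ac peaks and 34073 knockdown H3K27ac peaks on the autosomes and X, and 4453 SMARCB1 peaks.

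The first comparison asked how H3K27ac differed genome-wide between control and SMARCB1-knockdown cells. Most acetylated regions were found in both libraries, and 12163 of 19821 protein-coding genes carried H3K27ac within 1 kb of a gene end in both. At CCL2, which encodes a monocyte-attracting chemokine, a control peak of 3432 bp at chromosome 17, 34252068 to 34255499 (hg38), had no counterpart in the knockdown. KRT5, a keratin of basal epithelial cells, showed the opposite, with 3695 bp covered in the knockdown and 0 bp in the control within 10 kb of its ends. The KRT5 knockdown peaks overlapped the SMARCB1 peak with the second-highest value, which spanned the whole gene. These knockdown peaks may not reflect acetylated chromatin, a possibility taken up under the other observations. H3K27ac peaks covered 79.5 Mb in the control and 70.9 Mb in the knockdown, a ratio of 0.892, and 63.4 Mb was covered in both.

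Of the control peaks, 6259 of 35307 had no overlapping knockdown peak, or 17.7% (17.3 to 18.1%). Of the knockdown peaks, 4146 of 34073 had no overlapping control peak, or 12.2% (11.8 to 12.5%). Peaks found in 1 library only were narrow, with a median width of 626 bp for control-only and 501 bp for knockdown-only peaks, against 1982 bp and 1769 bp for shared peaks. When each list was ranked by width into 10 classes, the control-only share was 70.5% (69.0 to 72.0%) in the narrowest class and 0.0566% (0.0155 to 0.206%) in the widest. The knockdown-only share went from 52.0% (50.3 to 53.7%) to 0.293% (0.159 to 0.539%). Within the wider 50% of each list the order turned, with 1.08% of control peaks and 1.34% of knockdown peaks lacking a counterpart. Single-library peaks were less often at gene ends than shared ones, at 8.36% (7.70 to 9.07%) for control-only and 5.60% (4.94 to 6.34%) for knockdown-only peaks, against 37.6% (37.0 to 38.1%) for shared control peaks. These shares were not matched on width, and a wider peak reaches a gene end more easily, so position is not separated from width here.

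**Figure D1:**
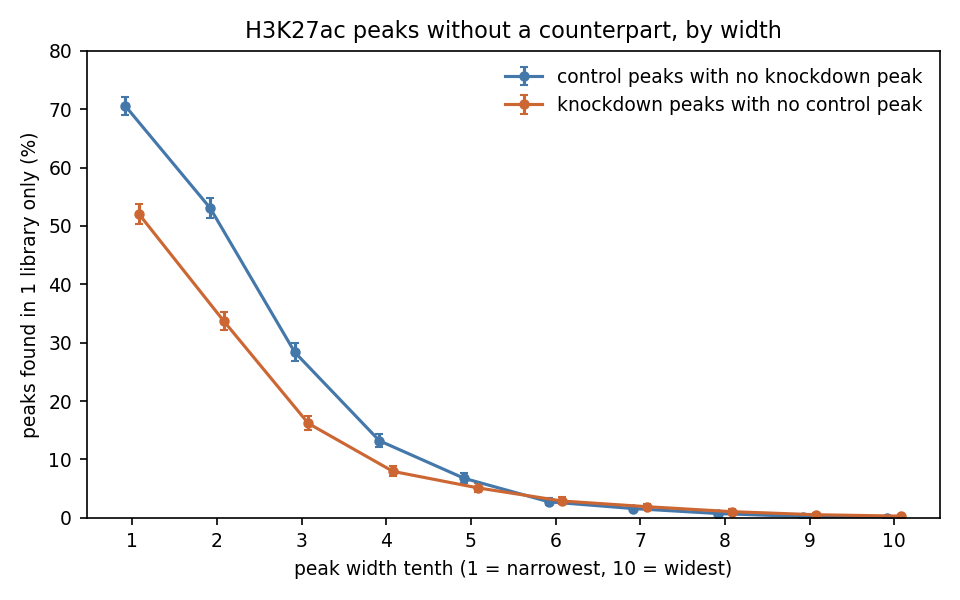
Percentage of H3K27ac peaks without an overlapping peak in the other library (vertical axis) in 10 classes of peak width from narrowest to widest (horizontal axis). Blue points are control peaks, orange points are knockdown peaks, and bars are 95% Wilson intervals. The control share falls from 70.5% to 0.0566% and the knockdown share from 52.0% to 0.293%.

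H3K27ac at a gene end was found in the control only for 432 protein-coding genes, or 2.18% (1.99 to 2.39%), and in the knockdown only for 149, or 0.752% (0.641 to 0.882%). These calls count peaks that reach within 1 kb of an end. A peak shared by both libraries can therefore mark a gene in 1 library only. With a window of 2.5 kb, 17 of the 24 genes named for the largest differences were still marked in 1 library only. The control-only genes with the largest difference in acetylated length within 10 kb of their ends were led by RIPK4, a receptor-interacting protein kinase, with 4821 bp in the control and 1158 bp in the knockdown. TNNI3, the cardiac troponin I gene, had 8125 and 4515 bp, and PBXIP1 had 8217 and 4647 bp. COL9A2, a collagen IX chain, went from 3553 bp to 0 bp, and DHRS3, a retinaldehyde reductase, from 3060 bp to 0 bp. FBLIM1, DAPK1, NTSR1 and NES, which encode a filamin-binding adaptor, a death-associated kinase, a neurotensin receptor and the intermediate filament nestin, kept between 2697 and 12547 bp of other acetylation nearby in the knockdown. The uncharacterised genes LOC124909439 and LOC124900940 completed the 12, with 13918 and 12642 bp in the control and 10572 and 9393 bp in the knockdown. The control peak of 18854 bp at LOC124909439 overlapped knockdown H3K27ac that did not reach the end window. Among knockdown-only genes, PTH1R, a parathyroid hormone receptor, led with 7340 bp in the knockdown and 1894 bp in the control. The wider of its knockdown peaks, of 4197 bp, overlapped control H3K27ac that did not reach the end window. AJAP1, which encodes an adherens junction-associated protein, had 5090 and 501 bp, and PRPSAP2 had 4413 and 1275 bp. RTL3, NHS, NHSL2, TMEM212 and SHC4 had no control H3K27ac within 10 kb of an end and between 2495 and 3157 bp in the knockdown. SIRPB1, MROH2B and GTF2IRD2 had 7737, 4292 and 3890 bp in the knockdown, against 4805, 1487 and 1392 bp in the control. When only the wider 50% of each list was kept, 962 genes were marked in the control only and 351 in the knockdown only, and 62 of the 432 and 18 of the 149 genes were among them. The differences at RTL3, NHSL2, SHC4 and PRPSAP2 were then 0 bp, and those at DAPK1, NTSR1 and KRT5 shrank to 764, 1654 and −1686 bp (control minus knockdown). Cutting both lists also turns a shared peak into a single-library peak where it passes the cut in 1 list only. The totals of 962 and 351 are therefore no check of the 432 and 149.

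**Figure D2:**
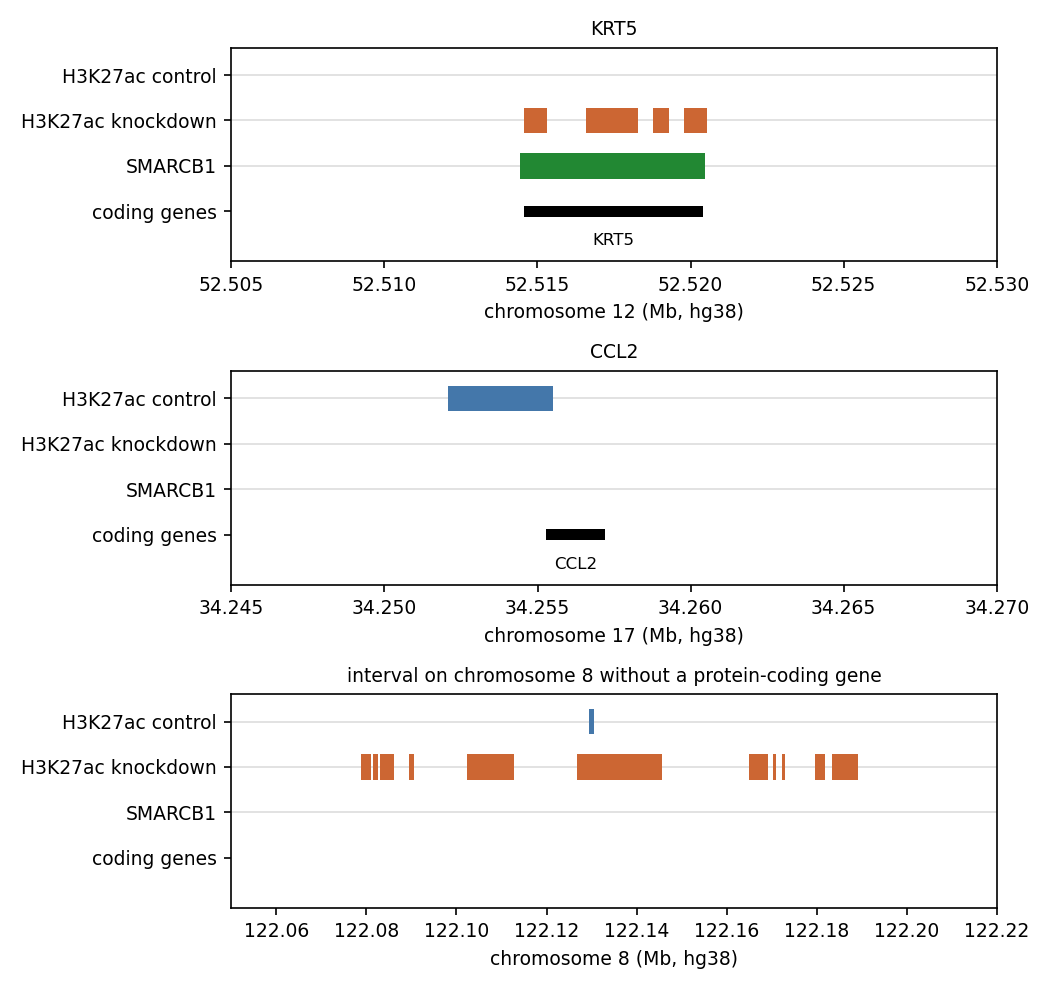
Peaks of the 3 lists (rows) along 3 intervals of hg38 (horizontal axes, Mb), with protein-coding genes in black. KRT5 carries knockdown H3K27ac peaks and a SMARCB1 peak and no control peak, CCL2 carries a control peak only, and the chromosome 8 interval has 1070 bp of control and 49837 bp of knockdown H3K27ac between 122078815 and 122189090.

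Genes were then grouped by 21 lists fixed in advance. Every member with H3K27ac at a gene end in either library had it in both for 12 of these groups of genes. They were SWI/SNF subunits (27 of 28 members), nucleoporins (28 of 29), cytosolic ribosomal proteins (43 of 43), cell cycle genes (31 of 34), Polycomb subunits (22 of 24), enzymes that add or remove H3K27 acetylation (11 of 11), and AP-1 and immediate early genes (16 of 18). The others were YAP and TEAD targets (20 of 22), cholesterol biosynthesis and uptake (24 of 28), hypoxia and glycolysis (21 of 24), interferon response and antigen presentation (21 of 23), and endothelial genes (3 of 21). Of all 12744 genes marked in either library, 12163 were marked in both. Random lists matched to these 12 had a mean of at most 0.959 control-only and 0.330 knockdown-only members, both for the interferon list. These 12 lists therefore do not stand out. FOSL1, an AP-1 subunit, had 22503 bp in the control and 21151 bp in the knockdown within 10 kb of its ends, and CRIM1, from the YAP and TEAD list, had 28849 and 24515 bp.

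The epithelial list had 2 of 12 marked members in the control only, CLDN3, a tight junction claudin, with 781 bp and EPCAM, an epithelial adhesion molecule, with 501 bp, both against 0 bp. This share lay at percentile 98.2 of 10000 random lists matched on H3K27ac width, with each tie counted as 0.5 here and in the list percentiles below, and 351 random lists were as high or higher. Replication-dependent histones had 2 of 30 in the control only, H1-1 and H1-5 (percentile 98.6, 269 as high or higher). In the knockdown only, the xenobiotic metabolism list had NQO1, a quinone reductase, and CYP3A5, a cytochrome P450, with 912 and 879 bp against 0 bp, or 2 of 13 (percentile 98.6, 265 as high or higher). The neural and neuroendocrine list had GFAP and STMN2, or 2 of 7 (percentile 99.6, 76 as high or higher), and the leukocyte list CD79A and CD4, or 2 of 7 (percentile 99.2, 167 as high or higher). Acetylated length within 10 kb was close in both libraries at GFAP (9589 bp in the control, 10848 bp in the knockdown) and CD79A (4649 and 4939 bp), and at CD4 it was higher in the control (3779 and 3591 bp). CD8A and CSF1R of the leukocyte list were marked in the control only (2 of 7, percentile 94.1), so its single-library members went both ways. The remaining lists had at most 1 member per direction: HOXA3 (1 of 23), CCL2 (1 of 21 inflammation and NF-kB genes) and COL1A2 (1 of 25 mesenchymal genes) in the control only, and TWIST2 of the mesenchymal list and FOXA2 of the hepatocyte list (1 of 8) in the knockdown only. UGT2B7, a glucuronosyltransferase of the xenobiotic list, was marked in both, with 3370 bp in the control and 13209 bp in the knockdown. With 21 lists compared in each direction, some can pass percentile 97.5 through the number of lists alone. Each of these lists rests on 1 or 2 genes. With each tie counted as 1, the epithelial, histone and xenobiotic lists did not lie above percentile 97.5. With a window of 2.5 kb the histone and neural lists no longer lay above it. Without matching on width, the epithelial and histone lists no longer did, and with the wider 50% of each list the differences in covered length at CLDN3, EPCAM, NQO1, CYP3A5, STMN2, CD8A, CSF1R, COL1A2 and FOXA2 were 0 bp. The wider 50% starts at 1707 bp in the control and 1601 bp in the knockdown. Covered length at all of these genes but COL1A2 was below that, so their 0 bp followed from the cut and is no check.

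The targeted gene was marked in both libraries. SMARCB1, on chromosome 22 from 23786966 to 23838009, had a control peak of 2341 bp and a knockdown peak of 1904 bp at an end, and no SMARCB1 peak there. An shRNA acts on the transcript, so acetylation of the locus does not check the knockdown. Every other SWI/SNF gene on the list except ACTL6B, a neuronal subunit without H3K27ac at an end, was also marked in both, and SMARCB1 peaks lay at the ends of BCL7A, BCL7B, BCL7C, BICRAL, BRD7, DPF2 and SMARCC2. Within 10 kb of its ends, ARID1A carried 18223 bp in the control and 16436 bp in the knockdown, SMARCA4 4033 and 2846 bp, and SMARCD1 3213 and 5017 bp. With the wider 50% of each list the differences at SMARCA4 and SMARCD1 turned, to −316 and 279 bp (control minus knockdown). NUP210, a nuclear pore gene, had a control peak of 1863 bp and a knockdown peak of 1478 bp at chromosome 3, 13419463 to 13420940, without a SMARCB1 peak at either end.

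The second comparison set the SMARCB1 peaks beside H3K27ac. SMARCB1 peaks lay mostly in acetylated chromatin, most often at promoters and 5' UTRs. Of the 1299 peaks the authors classed as promoter-TSS, 96.7% (95.6 to 97.5%) overlapped control H3K27ac, as did 97.0% (93.7 to 98.6%) of 203 peaks in 5' UTRs. The share was 61.9% (59.3 to 64.5%) of 1308 intron peaks, 55.7% (52.3 to 59.0%) of 826 intergenic peaks, 58.6% (54.0 to 63.0%) of 459 exon peaks and 22.2% (16.6 to 29.0%) of 171 peaks in 3' UTRs. Over the whole list 3143 of 4453 SMARCB1 peaks, or 70.6% (69.2 to 71.9%), overlapped control H3K27ac, and 3073, or 69.0% (67.6 to 70.4%), overlapped knockdown H3K27ac. Random positions on the same chromosomes gave 4.06% and 3.72%, so the observed shares were 17.4-fold and 18.5-fold higher. H3K27ac of both libraries lay under 3022 SMARCB1 peaks, of the control only under 121, of the knockdown only under 51, and of neither under 1259.

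Several of the highest SMARCB1 values lay on keratin, translation factor, actin and non-coding RNA genes, whose RNA levels were not analysed here. The 10 peaks chosen by the authors' value, 1 per nearest protein-coding gene, included KRT5 and KRT17, keratins of stratified epithelia, EEF1A1, a translation elongation factor, and ACTB, cytoplasmic actin. Another 5 lay on non-coding RNA genes: RN7SL2 (nearest coding gene NEMF), RN7SL1 (RPS29), RN7SK (GSTA4), RPPH1 (PARP2) and RMRP (CCDC107). The SMARCB1 peak at KRT5 covered chromosome 12, 52514442 to 52520461, and that at KRT17 chromosome 17, 41619343 to 41624751. Neither overlapped control H3K27ac, and both overlapped knockdown H3K27ac. Of the 100 peaks with the highest values, 49% (39.4 to 58.7%) overlapped control H3K27ac, against 86.2% (83.8 to 88.3%) for ranks 101 to 1000 and 71.1% (69.7 to 72.4%) for all ranks from 101. The share fell again towards the lowest values, to 59.6% (57.7 to 61.6%) for ranks 2001 to 4453. Peaks classed as exon, 3' UTR, TTS or non-coding made up 50% (40.4 to 59.6%) of these 100, 24% (21.3 to 26.9%) of ranks 101 to 1000 and 15.5% of ranks 2001 to 4453.

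**Figure D3:**
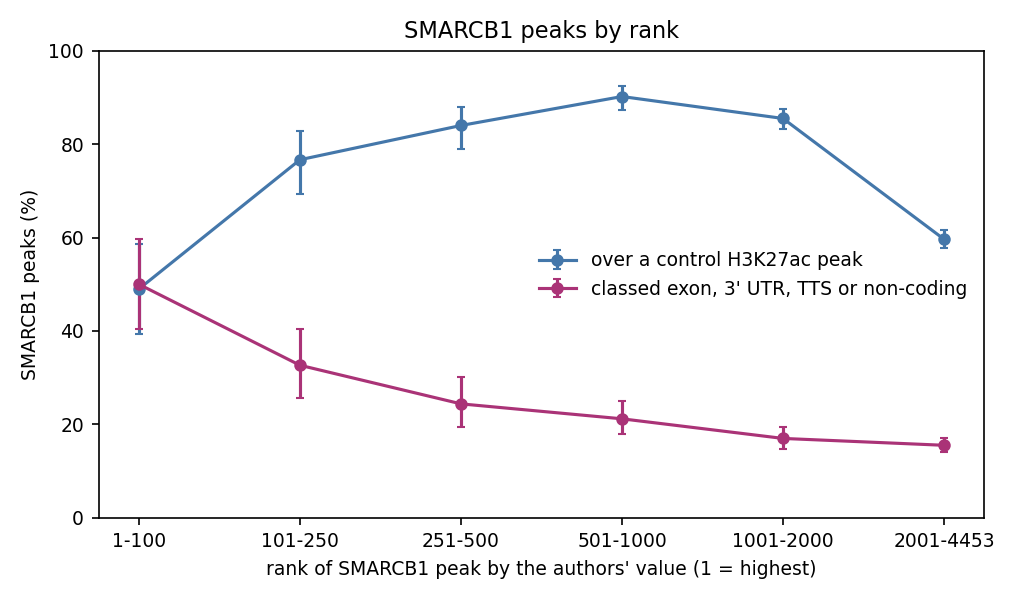
Percentage of SMARCB1 peaks (vertical axis) by rank of the authors' value (horizontal axis, 1 is the highest). Blue points are peaks over control H3K27ac, purple points are peaks the authors classed as exon, 3' UTR, TTS or non-coding, and bars are 95% Wilson intervals. The blue share is 49% for ranks 1 to 100, 90.2% for ranks 501 to 1000 and 59.6% for ranks 2001 to 4453.

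Cytosolic ribosomal protein genes stood out among the 21 lists for SMARCB1 peaks at gene ends, with 28 of 43 members against a mean of 9.90 in random lists and 0 of 10000 random lists as high. RPL3 and RPLP0 were among the members with a SMARCB1 peak at an end. Hypoxia and glycolysis genes followed with 10 of 21 against 4.89 (percentile 99.1, 140 as high or higher), among them ENO1 and PKM, which encode glycolytic enzymes. When only peaks of the promoter-TSS class were counted, 7 ribosomal protein genes and 4 hypoxia and glycolysis genes remained, against 5.72 and 2.70 in random lists. HOX genes (1 of 23 against 4.79, percentile 1.70) and inflammation and NF-kB genes (1 of 21 against 4.39, percentile 2.47) had few SMARCB1 peaks at their ends, but counted by the promoter-TSS class alone they lay at percentiles 15.4 and 17.7. The other 17 lists lay between percentiles 9.83 and 96.7.

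The third comparison asked whether acetylated regions with a SMARCB1 peak were more often without a counterpart in the knockdown. They were found again more often than other regions. Of 3055 control H3K27ac peaks with a SMARCB1 peak, 86 had no knockdown peak, or 2.82% (2.29 to 3.46%), against 19.1% (18.7 to 19.6%) of 32252 peaks without one. Peaks with SMARCB1 were wider, with a median of 2513 bp against 1618 bp. In 10000 draws of peaks without SMARCB1, matched on width class and on position at a gene end, the mean share was 4.34% and the range 3.14 to 5.53%, so the difference was −1.53 percentage points and 0 of the draws were as low as the observed share. Within the wider 50% of control peaks the difference was −0.419 points, and with 50 width classes it was −1.40 points. The same held for knockdown peaks, of which 45 of 3005 with SMARCB1, or 1.5% (1.12 to 2.0%), had no control peak, against a matched mean of 3.04%. That difference, −1.54 points, was about as large as the one for control peaks. Peak height was not available for matching, here or at gene level below. A remaining difference in peak strength therefore cannot be told apart from a link to SMARCB1.

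At gene level, 26 of 2417 genes with control H3K27ac and a SMARCB1 peak at an end were marked in the control only, or 1.08% (0.735 to 1.57%), against 406 of 10178 genes without one, or 3.99% (3.63 to 4.39%). Genes with SMARCB1 had wider control peaks at their ends (median 2744 bp against 2317 bp), and in 10000 draws of genes without SMARCB1, matched on that width, the mean share was 2.30% and the range 1.41 to 3.23%, so the difference shrank from −2.91 to −1.22 percentage points. The 10 with the largest difference in acetylated length were ITGB7, an integrin chain, PRDX2, a peroxiredoxin, CRHR1, a corticotropin-releasing hormone receptor, CSF3R, the receptor for granulocyte colony-stimulating factor, HTRA1, a serine protease, SGCA, LARGE2, INPP4B, SH3GL3 and IQGAP2. ITGB7 had 3428 bp in the control and 1059 bp in the knockdown, and CRHR1, HTRA1, INPP4B and SH3GL3 had between 1305 and 1928 bp in the control and 0 bp in the knockdown. With the wider 50% of each list the differences at ITGB7, HTRA1, INPP4B and SH3GL3 were 0 bp and that at LARGE2 went from 1464 to 140 bp, while that at CRHR1 stayed at 1928 bp and those at SGCA and IQGAP2 grew to 2820 and 1735 bp. Covered length at HTRA1, INPP4B and SH3GL3 was below the 1707 bp at which the wider 50% of control peaks starts, so their 0 bp followed from the cut. The SMARCB1 peak overlapped a control H3K27ac peak at an end of ITGB7, SGCA, LARGE2, INPP4B, SH3GL3 and IQGAP2. At CRHR1, CSF3R and HTRA1 the SMARCB1 peak lay at the opposite end of the gene, and at PRDX2 it lay beside the acetylated peak. The control peak of 3446 bp at CSF3R overlapped knockdown H3K27ac that did not reach the end window.

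Chromosome 17 stood apart in the SMARCB1 list and among single-library H3K27ac peaks. It held 10.7% (9.79 to 11.6%) of SMARCB1 peaks and 5.15% of control H3K27ac peaks. Of the H3K27ac peaks found in 1 library only, 390 of those on chromosome 17 were knockdown-only and 267 control-only, so 59.4% (55.6 to 63.1%) were knockdown-only. Chromosome 14 followed with 53.8% (47.8 to 59.7%), and chromosome 7 was lowest with 28% (24.2 to 32.2%). Knockdown-only genes on chromosome 17 included PRPSAP2 and GFAP, and control-only genes there included CCL2, CRHR1 and SGCA.

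**Figure D4:**
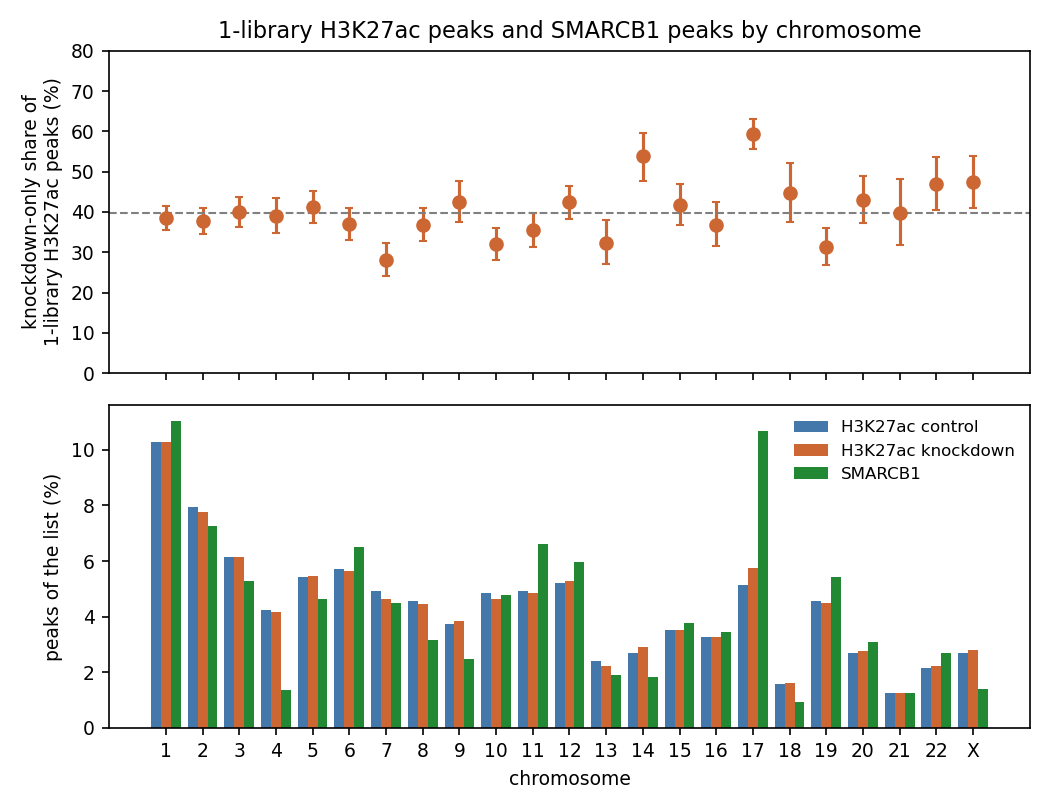
Top, percentage of single-library H3K27ac peaks that are knockdown-only on each chromosome (vertical axis), with 95% Wilson intervals and a dashed line for all chromosomes together. Bottom, percentage of each list's peaks on each chromosome (bars, vertical axis), where chromosome 17 holds 10.7% of SMARCB1 peaks and 5.15% of control H3K27ac peaks.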

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

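The settings that leave out SMARCB1 peaks, knockdown peaks touching SMARCB1 or chromosomes 14 and 17, and those with 50 width classes, genes matched on width or the promoter-TSS class alone, were chosen after the data were seen. Values are given in the order control peaks without a knockdown peak, knockdown peaks without a control peak, and SMARCB1 peaks over control and over knockdown H3K27ac. Requiring an overlap of 50% of the shorter peak gave 18.4, 12.9, 68.8 and 67.0%. Counting any peak within 1 kb as shared gave 15.4, 10.6, 73.7 and 72.2%. Keeping the wider, or for SMARCB1 the higher-valued, 50% of the first list gave 1.08, 1.34, 82.6 and 82.1%, and of both lists 14.5, 9.62, 66.7 and 62.9%. Merging peaks closer than 1 kb gave 16.0 and 11.5% for the H3K27ac shares. Leaving out SMARCB1 peaks in exon, 3' UTR, TTS or non-coding classes gave 74.9 and 73.2% over H3K27ac. Knockdown peaks without a control peak made up 11.6% without chromosomes 14 and 17 and 13.2% without peaks touching SMARCB1. The difference between control peaks with and without SMARCB1 stayed negative under every setting run, at −16.3 points without matching and −0.419 points in the wider 50% of control peaks; matching on width was already the main analysis.

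With a 2.5 kb window, 57.1% of SMARCB1, 35.6% of control and 36.1% of knockdown H3K27ac peaks lay at gene ends, and with the upper 50% of each list 63.3, 45.8 and 44.2%. With the upper 50%, 962 genes were marked in the control only and 351 in the knockdown only, counting shared peaks that passed the cut in 1 list only. Of the 432 and 149 genes, 330 and 118 were also single-library genes with the 2.5 kb window. Of the 24 genes named for the largest differences in covered length, 17 were. Only 1 list lay above percentile 97.5 (a tie counted as 0.5) for control-only genes with a 2.5 kb window (epithelial) and 1 without matching (leukocyte), against 2 in the main analysis; with each tie counted as 1 these were 0, 1 and 0. The control minus knockdown difference in covered length was recomputed at 79 named genes. With the upper 50% it changed sign at 6, to 279 bp at SMARCD1, −316 bp at SMARCA4, −445 bp at SMARCB1, 110 bp at BRD9, −25 bp at ARID1B and −29 bp at SMARCD3, became 0 bp at 19 and moved without changing sign at 60, these 19 included. Merging changed the sign at SMARCB1, to −559 bp, and moved 16 others. The cause was not tested, except that keeping wider peaks of both lists removes narrow peaks and splits some shared ones by construction. Motif searches in both window sizes and with the upper 50%, and 1 transcript start per gene, were not run. No paired analysis was possible because each group had 1 library. The effect of depth was not tested by thinning reads, and the depth of the SMARCB1 library is unknown.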

Other observations

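All tests in this part were chosen after the results were seen. The regions named in the next paragraph were also chosen after their values were seen.

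Of 1621 single-library H3K27ac peaks over 1000 bp, 170 lay in 47 clusters, taken here as at least 3 such peaks of the same kind with gaps under 100 kb. On chromosome 8, 8 knockdown-only peaks over 1000 bp lay between 122078815 and 122189090, where H3K27ac covered 1070 bp in the control and 49837 bp in the knockdown. The widest of them spanned 10478 bp, and HAS2, a hyaluronan synthase gene, was the nearest protein-coding gene at 461 kb. A second knockdown cluster of 4 peaks on chromosome 15, from 98065930 to 98155933, had 1160 and 21980 bp. At ADGRB3, an adhesion receptor gene, a cluster of 4 peaks had 0 bp in the control and 11736 bp in the knockdown. In the control only, 8 peaks lay between 130214831 and 130422899 on chromosome 8 across ASAP1, which encodes an Arf GTPase-activating protein, with 55580 bp in the control and 24732 bp in the knockdown. Smaller control clusters lay in DST, a cytolinker gene, with 19764 and 9143 bp, and in DNMBP with 7780 and 0 bp. CD44, a hyaluronan receptor gene, had 21654 and 10530 bp over its cluster.

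Several SMARCB1 peaks of highest value lay on keratin, translation factor, actin and non-coding RNA genes, with KRT5 at rank 2, KRT17 at rank 4 and KRT14 at rank 16. SMARCB1 bound at acetylated regulatory DNA does not account for all of the top 100, of which 49% overlapped control H3K27ac against 86.2% of ranks 101 to 1000 and 71.1% of all later ranks, although the share was also low at ranks 2001 to 4453 (59.6%). Material from keratinocyte-type cells is a candidate source, but the gene counts cannot tell RNA or cDNA from chromatin of such cells. Of 30 keratinocyte genes, 19 had a SMARCB1 peak away from control H3K27ac. Of the 19 genes not looked at before the list was written, 11 had one (0.822 in length-matched random genes). However, 18 of the 30 carried control H3K27ac and 1 was on another list. Among those without control H3K27ac, 9 of 12, and 5 of the 8 not looked at before, had such a peak (0.221 and 0.157 in random genes without it). Hepatocyte (0 of 28), leukocyte (0 of 18), neural (2 of 18) and endothelial (1 of 21) genes stayed within random limits. Transcripts of genes expressed in all cells may add to it. Such peaks lay in 19 of 43 ribosomal protein genes against 1.17 in random genes, and in 8 of 24 hypoxia and glycolysis genes against 1.01. Of the top 100, 12% lay over knockdown-only H3K27ac (7.0 to 19.8%) against 0.896% of later ranks. They included the peaks at KRT5, KRT17, RN7SL2, RN7SL1, RPPH1 and RMRP. Some of the same material may lie in the knockdown library, so the knockdown H3K27ac at KRT5 may not be a gain of acetylation. Among keratinocyte genes, however, knockdown-only H3K27ac lay in 5 of 30, and in 1 of the 19 not looked at before. It lay in 4 of 21 endothelial, 2 of 18 leukocyte, 2 of 18 neural and 1 of 28 hepatocyte genes. These counts, not matched on gene length, do not set keratinocyte genes apart in the knockdown library. Unspecific recovery of highly transcribed DNA and SMARCB1 binding along transcribed genes were not tested and stay open, the latter as the biological explanation.

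Control-only and knockdown-only H3K27ac peaks were unevenly spread along the genome, with the knockdown-only share of loci in 10 Mb bins varying with 1.30 times the binomial variance, a value that 1 of 10000 shuffles reached. The spread was thus not above every shuffle, the limit set for setting aside local changes independent of their neighbours. Shared peaks were mostly narrower in the knockdown, with a median log2 width ratio (knockdown over control) of −0.132 over 27387 pairs. Bins with more knockdown-only loci had a higher ratio, so mostly less narrowing (Spearman rho 0.454 over 199 bins, 0.409 without chromosome 17, largest shuffle 0.280). That goes against such local changes. The shuffles treat bins as independent, however, so such changes are not excluded. A regional shift between the libraries, such as a DNA copy number difference, may account for the uneven spread. Neither the shared input nor any value used here separates copy number from broad chromatin change after SMARCB1 knockdown. The SMARCB1 library did not follow the same bins, with rho −0.0486 outside chromosome 17 and 0.0262 with it, so its excess of peaks on chromosome 17 remains unexplained. Bins are not independent replicates.

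H3K27ac peaks found in 1 library only were narrow. The lower tag total of the knockdown library may account for control-only peaks among the narrower ones, where the control-only share exceeded the knockdown-only share in 5 of 5 width classes with intervals apart. That order repeats the shares over all peaks, 17.7 and 12.2%. A loss of H3K27ac in the knockdown would give it too, so it cannot decide for depth. For peaks over 2000 bp the knockdown-only percentage was 53.1% (46.4 to 59.6%), so depth and a change in the knockdown cannot be told apart there, because the interval spans 50%. Of 6 minimum widths counted, the interval lay above 50% at 3000 bp alone, with 24 knockdown-only and 10 control-only peaks. Neighbouring peaks were counted separately, and several of the widest knockdown-only peaks lay in the chromosome 8 cluster, so these intervals are too narrow. Shared peaks over 2000 bp numbered 14327 in the control and 12558 in the knockdown, so 50% is not the value expected at equal rates. A difference caused by SMARCB1 knockdown was not tested separately from the libraries and stays open.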
